A study of Mus musculus with 3 samples.

How the data were processed

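RNA sequencing of 3 libraries was analysed, 1 each from mouse visceral adipose fibroblasts kept with vehicle, for which no time is given, or for 24 h with Osm at 3 ng/mL or TGF-beta1 at 3 ng/mL. The groups were taken from the sample titles and treatment labels. Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads, fragmented and copied with random primers. The protocols describe library types with and without strand information and do not say which was made, so reads of genes that overlap on opposite strands cannot be told apart. Genes that overlap another annotated gene were looked up in the file's own coordinates.

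The authors deposited a table of whole-number read counts per Ensembl gene and a table of FPKM values for the same genes. The submitters' processing notes name CASAVA, HISAT2, HISAT and TopHat2, without versions or roles, and the genome build mm39. The read counter, the annotation release and any filter on reads are not given in the sources used here. The counts were used as deposited. The authors' deposited FPKM values equal the counts divided by gene length and by an effective library size, which the values show to be the DESeq2 size factor of each library times the geometric mean of the count totals. The FPKM values served only as an alternative. Chromosome positions are those of the deposited table. The genome reference at hand was of an earlier build, so its coordinates were not used. Its transcript sequences served to measure what share of a gene's 50-base windows, of which 1 in 10 was sampled, occur in a transcript of another gene, as a measure of reads that the authors' counting could have split between near-identical copies.

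The table lists 56748 genes, 23539 of them with any count. Count totals were 18336068, 17319872 and 18533741 for vehicle, Osm and TGF-beta1. Protein-coding genes took 98.4%, 98.4% and 98.6% of the counts and ribosomal RNA genes 0.232%, 0.255% and 0.182%. Counts were scaled to CPM with the TMM factors of edgeR 4.0.16 in R 4.3.3 (1.00, 1.00 and 0.995). Genes with at least 1 CPM in at least 1 library were tested, 13712 in all. The other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and DESeq2 1.42.0 gave the alternative size factors.

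With 1 library per condition no error between cultures can be estimated, so no model was fitted and no p-value is given. A gene was counted as at least 2-fold higher or lower where its log2 ratio of CPM, computed with a prior count of 0.5, was at least 1 in size and the exact 95% interval of the ratio of counts (conditional binomial, Clopper-Pearson) excluded a ratio of 1. The interval compares 2 libraries and not the conditions. It covers counting error only. The reads carry no molecular identifiers, so repeat reads of the same molecule cannot be told apart and the interval may be too narrow. The floor for a count of 0 was 3 counts, which is 0.163, 0.173 and 0.163 CPM in the vehicle, Osm and TGF-beta1 libraries. The comparisons were Osm over vehicle, TGF-beta1 over vehicle and Osm over TGF-beta1.

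The 32 gene lists, 25 of pathways and 7 of cell type markers, were fixed before the data were examined, and 805 of their 808 symbols were found. The pathway lists were collagen chains, collagen processing and crosslinking, other matrix proteins, proteases and inhibitors of matrix turnover, integrins and focal adhesion genes, myofibroblast contractile genes, TGF-beta/Smad response genes, gp130/Stat3 response genes, and receptors and signal transducers of both ligands. They also covered AP-1 and immediate early genes, complement and acute-phase genes, chemokines and cytokines, interferon response genes, Wnt and BMP pathway genes, growth factors and the IGF axis, adipose stromal progenitor genes, adipogenic genes, cholesterol synthesis and glycolysis. The others were nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, the unfolded protein response, antioxidant genes, cell cycle genes and reference housekeeping genes. The cell type lists were of leukocytes, endothelial, erythroid, mesothelial, mural and Schwann cells and mature adipocytes. For each list with at least 5 measured members, the median log2 ratio was given its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart below percentile 2.5 or above 97.5. This is a description of these libraries, not a test.

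The rule for named genes was also fixed before the data were examined. It took, per comparison, the 10 highest and 10 lowest log2 ratios among protein-coding genes with at least 10 CPM in either library that passed the 2-fold rule. From each list it took up to 4 members, the 2 with the largest ratios among those with at least 5 CPM and the 2 with the highest mean level. It always took a fixed set that included Socs3, Osmr, Timp1, Il6, Ccn2, Acta2, Col1a1, Col1a2 and Col3a1. Some genes that the rule takes are not reported here. It also took up to 5 genes per direction with the largest shared and the largest opposite differences from vehicle, at 10 CPM or more in at least 1 library. Genes named outside this rule are said to be so.

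Because both ligands were set against the same vehicle library, the overlap, correlation and covariance of the ratios were set beside 100 simulations of unchanged libraries, with counting error alone and with assumed coefficients of variation of 0.1 and 0.2. The counting rule was tested on simulated counts with 200 genes changed and counting error alone. Of 67 genes changed 3-fold it recovered 95.5% for Osm over vehicle (13476 genes tested), 97.0% for TGF-beta1 over vehicle (13466) and 97.0% for Osm over TGF-beta1 (13497). Of 66 changed 6-fold it recovered 98.5%, 100% and 98.5%, and of 67 changed 1.5-fold 2.99%, 0% and 4.48%, in the same order. Unchanged genes were counted in 0.377%, 0.317% and 0.346% of cases. These shares hold for counting error alone. With an assumed coefficient of variation of 0.2, unchanged libraries gave a mean of 221.9 genes higher and 222.3 lower for Osm over vehicle. The list rule set apart 8 of 200 unshifted lists and 200 of 200 shifted by 0.3. These lists were random genes from Osm over vehicle, so they do not show how lists of related genes behave.

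Alternatives fixed before the data were examined were total counts, DESeq2 size factors, upper-quartile factors, a library size without the mitochondrial and 20 most abundant genes, the authors' FPKM with a pseudocount of 0.1, no filter, a filter at 5 CPM, prior counts of 2 and 5, protein-coding genes only, folds of 1.5 and 4, and an interval wholly beyond 2-fold. A filter at 10 CPM was added after seeing the data.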

Results

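Fibroblasts from the visceral fat of wild-type mice on a high-fat diet were profiled by RNA sequencing with vehicle or after 24 h with recombinant mouse oncostatin M (Osm, 3 ng/mL) or recombinant human transforming growth factor beta 1 (TGF-beta1, 3 ng/mL). No time is given for the vehicle library. Osm is a cytokine of the interleukin 6 family that signals through gp130 and Stat3, and TGF-beta1 is the classical inducer of matrix production in fibroblasts. The cells came from the stromal vascular fraction, the non-adipocyte cells of the fat pad, and had been depleted by magnetic sorting of cells carrying CD45, CD31 or Ter119. The series concerns the signals between macrophages and fibroblasts in the fibrosis of obese adipose tissue, and the comparisons ask what each ligand did to these cells. There was 1 library per condition, so no difference below has a replicate check, and each interval is an exact 95% interval that covers counting error only. The vehicle, Osm and TGF-beta1 libraries held 18336068, 17319872 and 18533741 counted reads and 20702, 20501 and 20346 genes with any count. Mitochondrially encoded genes took 1.39%, 1.33% and 1.36% of the counts and the 20 most abundant genes 10.9%, 11% and 11.2%. A count of 0 allowed a level of up to 0.163, 0.173 and 0.163 CPM (scaled read counts relative to library size), and 13712 genes reached 1 CPM in at least 1 library.

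The Osm library differed little from the vehicle library, with 77.8% of tested genes within 1.2-fold. Members at least 2-fold higher were few: 2 of 37 gp130/Stat3 response genes and 2 of 16 complement and acute-phase genes, Saa3 and Serpina3n in both lists. Serpina3n, an acute-phase serine protease inhibitor (ENSMUSG00000021091, chromosome 12, 104372988 to 104380588, build mm39), was at 192.8 CPM with vehicle and 397.1 CPM with Osm, 2.06-fold higher (1.98 to 2.15). The acute-phase apolipoprotein gene Saa3 was 3.20-fold higher (2.28 to 4.65), but at a low level, 2.39 CPM with vehicle and 7.72 CPM with Osm. Socs3, the feedback inhibitor of gp130 signalling (chromosome 11, 117856905 to 117860873), was 1.61-fold higher (1.48 to 1.74), short of the 2-fold rule. The interstitial collagens stayed close to vehicle, with Col1a1 at 4285 CPM with vehicle and 4023 CPM with Osm, Col1a2 at 4302 and 4032 CPM, and Col3a1 at 6175 and 7276 CPM.

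In all, 130 genes were at least 2-fold higher with Osm and 89 at least 2-fold lower, of which 48 and 54 were protein-coding. Few of them were abundant: at 10 CPM or more in either library, 6 genes were higher and 4 lower. The protein-coding genes among these 10 were Serpina3n, Rps27a, Csmd1, Gapdh, Sumo2 and Aspn. Csmd1, a large membrane protein with complement-control domains (chromosome 8, 15942537 to 17585602), was 2.01-fold higher (1.60 to 2.54). Aspn, which encodes the small proteoglycan asporin (chromosome 13, 49697919 to 49721041), was 2.25-fold lower (1.83 to 2.78). Gapdh (chromosome 6, 125138678 to 125143430) was at 58.3 CPM with vehicle and 6.74 CPM with Osm, 8.62-fold lower (7.14 to 10.6), while the glycolysis genes Aldoa and Pkm were at 1166 and 1636 CPM with vehicle. Sumo2 was 3.62-fold lower (3.12 to 4.23) and the ribosomal gene Rps27a was 2.01-fold higher (1.90 to 2.12). Gapdh, Sumo2 and Rps27a have near-identical copies elsewhere in the genome, with 20.8%, 17.7% and 22.9% of their 50-base windows found in a transcript of another gene, so their values are uncertain. Most genes with sharing of this size did not differ 2-fold, but such differences were more frequent among them. At 10 CPM or more in either library, 6 of 466 genes with at least 20% of windows shared differed 2-fold, against 4 of 8712 with less. This count was made after the result was seen. The 6 were Gapdh, Rps27a and the 4 processed pseudogenes given below, while Sumo2 lay just under the 20%. For protein-coding genes the contrast therefore rests on Gapdh and Rps27a. Among genes without a 2-fold difference, Pkm, with 26.6% shared, was 1.07-fold higher (1.05 to 1.09). Fdps, with 28.8%, was 1.23-fold higher (1.07 to 1.43) and Ftl1, with 50.4%, 1.04-fold higher (1.03 to 1.06). Gapdh is also overlapped on the opposite strand by Iffo1, at 19.5 CPM with vehicle and 20.9 CPM with Osm, above Gapdh in the Osm library. The remaining 4 of the 10 were processed pseudogenes, Gm10241, Gm6344, Gm9824 and Gm12751, with 100%, 95.9%, 50% and 100% of windows shared.

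Of the 28 gene lists with at least 5 measured members, 2 stood above and 3 below the central 95% of random lists matched on expression. By chance 1.4 would do so if the members of a list varied independently and lists shared none. The 2 lists above share Hp, Lbp, Lcn2, Saa3 and Serpina3n, so 1.4 is only a rough guide. The gp130/Stat3 response genes had a median log2 ratio of 0.22 (percentile 100), with 31 of 37 measured members above 0, 2 of them at least 2-fold higher and none at least 2-fold lower. Timp1, an inhibitor of matrix metalloproteinases, went from 604.4 to 771.5 CPM (1.28-fold, 1.25 to 1.31), and Il6st, which encodes gp130 itself, from 703.6 to 742.0 CPM. The complement and acute-phase genes had a median of 0.13 (percentile 99.98), with 13 of 16 members above 0. Saa3 and Serpina3n passed the 2-fold rule there, while the abundant C4b (1.17-fold, 1.15 to 1.19) and Serping1 (1.08-fold, 1.06 to 1.10) did not. C4b shares 36.8% of its windows with another gene.

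The lists below the random range were the adipose stromal progenitor genes, the collagen chains and the myofibroblast contractile genes. The progenitor genes had a median of -0.13 (percentile 0) with 21 of 25 members below 0 and none past the 2-fold rule. Dpp4, a surface marker of interstitial progenitors, was 1.46-fold lower (1.34 to 1.60) and Cd55 1.36-fold lower (1.27 to 1.46). The collagen chains had a median of -0.09 (percentile 0.01), with 16 of 22 below 0. Only Col8a2 (chromosome 4, 126180586 to 126208123) passed the rule among them, at 8.91 CPM with vehicle and 3.63 CPM with Osm, 2.44-fold lower (1.83 to 3.34). The myofibroblast genes had a median of -0.05 (percentile 2.25), just under a random range that reached down to -0.05, and 15 of 22 members were below 0. Acta2, the smooth muscle actin gene that marks myofibroblasts (chromosome 19, 34218490 to 34232990), was at 445.6 CPM with vehicle and 421.7 CPM with Osm. Myl9 was 1.28-fold lower (1.2 to 1.37).

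The other 23 lists lay within the random range, with medians between -0.15 for the endothelial markers and 0.04 for the receptors and signal transducers of both ligands. Among the receptors, Osmr was 1.17-fold higher with Osm (1.13 to 1.2). In the TGF-beta/Smad list, none of 31 members passed the 2-fold rule. Ccn2, the connective tissue growth factor gene, was 1.06-fold lower (1.04 to 1.08). The cytokine gene Il6 was low in both libraries, at 6.79 and 6.11 CPM. In the growth factor list, Igfbp5 (chromosome 1, 72897091 to 72914043) was 1.91-fold lower (1.79 to 2.04) and Angptl4 1.56-fold higher (1.40 to 1.74), both short of the rule. Sdc1 was 1.46-fold higher (1.40 to 1.52), Timp3 1.42-fold lower (1.35 to 1.49), Fmod 1.66-fold lower (1.30 to 2.13) and the chemokine gene Cxcl5 1.45-fold higher (1.30 to 1.62). Members past the 2-fold rule that were named only after their values were seen were Rsad2 in the interferon list (log2 ratio 1.57), Rgs4 among the mural cell markers (-1.36) and Fbn2 among the other matrix proteins (-1.05).

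Unchanged libraries simulated with counting error alone gave no 2-fold difference at 10 CPM or more, where 10 were observed, and a mean of 45.9 below 10 CPM, where 209 were observed. With an assumed coefficient of variation between cultures of 0.1, unchanged libraries gave a mean of 0.22 such genes at 10 CPM or more and 79.0 below, fewer than observed, and with 0.2 a mean of 181 and 263.2, more than observed. The spread of the ratios of the 3830 genes at 50 CPM or more corresponded to a coefficient of variation of 3.25% per library.

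**Figure D1:**
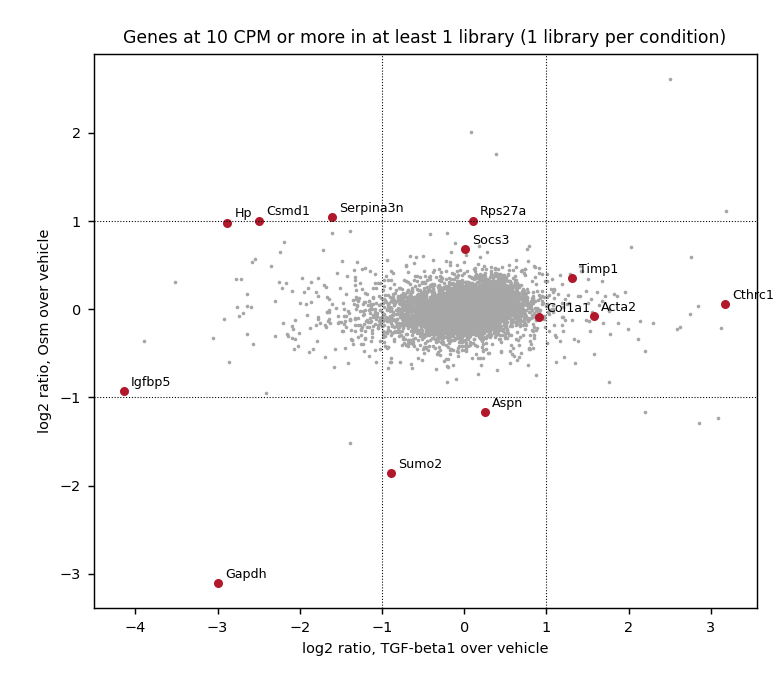
Log2 ratio over vehicle of each gene with at least 10 CPM in at least 1 library (9358 genes, 1 point each), with the TGF-beta1 library on the x axis and the Osm library on the y axis; dotted lines mark ratios of 2-fold and 13 named genes are labelled. Points spread further along the TGF-beta1 axis than along the Osm axis, and Serpina3n and Csmd1 lie 2-fold or more above vehicle for Osm and 2-fold or more below it for TGF-beta1.

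The TGF-beta1 library had 53.3% of tested genes within 1.2-fold of vehicle. Of the complement and acute-phase genes 14 of 16 were at least 2-fold lower and of the adipogenic genes 8 of 22, while 2 of 22 contractile genes were at least 2-fold higher. Acta2 was at 445.6 CPM with vehicle and 1327 CPM with TGF-beta1, 2.98-fold higher (2.90 to 3.05), and Tagln, which encodes the actin-binding protein transgelin, was 2.86-fold higher (2.77 to 2.94). Lox, whose product crosslinks collagen, went from 2667 to 8606 CPM (3.23-fold, 3.19 to 3.26). Col1a1 (chromosome 11, 94827050 to 94843868) was 1.88-fold higher (1.86 to 1.89) and Col1a2 1.33-fold higher (1.32 to 1.34), while Col3a1 was 1.08-fold lower (1.07 to 1.09). Tagln, Lox, Ccn2, Timp1, Timp3, Col14a1, Fn1 and Ccna2 each overlap another annotated gene on the opposite strand, and Col1a2 and Kng2 overlap one on the same strand. The strand used in counting is not given in the sources used here. With vehicle, the overlapping gene was at 19.1 CPM for Lox and at 1.74 CPM for Col1a2, which was itself at 4302 CPM. Exosc9, which overlaps Ccna2, was at 28.3 CPM with vehicle, above Ccna2 at 4.95 CPM.

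At least 2-fold differences were found in 968 genes, 311 higher and 657 lower with TGF-beta1, and 266 and 484 of these were protein-coding. At 10 CPM or more in either library, 93 were higher and 220 lower. Simulated unchanged libraries with an assumed coefficient of variation of 0.2 gave a mean of 89.5 higher (67 to 117) and 89.1 lower (67 to 118) at that level, so the number higher lay within their range and the number lower above it. With 0.1 the means were 0.13 and 0.07. For Osm over vehicle, 0.2 gave a mean of 181 genes either way at that level, where 10 were observed. A value of 0.2 is thus larger than those libraries allow, while the spread of the TGF-beta1 culture was not measured. Among protein-coding genes at 10 CPM or more, the largest differences upward were in Sorcs2, a sortilin-family receptor (9.13-fold, 6.48 to 13.6), and Cthrc1, a secreted protein of activated fibroblasts (chromosome 15, 38940327 to 38950516; 9.0-fold, 6.92 to 12.1). Next came the proteoglycan gene Cspg4 (8.75-fold, 7.44 to 10.4), Col8a2 (7.27-fold, 6.18 to 8.63), the adhesion molecule gene Ncam1 (7.19-fold, 6.56 to 7.90) and the growth factor gene Pdgfc (6.79-fold, 5.10 to 9.38). Notch4, Adamts8, the laminin chain Lama1 and the microfibril protein Mfap4 were 6.18-fold, 6.02-fold, 4.92-fold and 4.60-fold higher. Ncam1 and Mfap4 overlap genes on the opposite strand.

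Within the same set, the largest difference downward was in Igfbp5, an insulin-like growth factor binding protein, at 147.0 CPM with vehicle and 8.30 CPM with TGF-beta1, 17.7-fold lower (15 to 21). The aldehyde oxidase gene Aox3 was 14.9-fold lower (8.68 to 30.6) and Plin4, a lipid droplet coat protein, 8.31-fold lower (6.68 to 10.6). Plin4 is uncertain, since Hdgfl2, which overlaps it on the opposite strand, was at 43.1 CPM with vehicle and 40.3 CPM with TGF-beta1. Gapdh was 7.99-fold lower (6.70 to 9.67), with the same uncertainty as above. Hpca, the haptoglobin gene Hp, Nptx1, Ppl and Ahsg were 7.58-fold, 7.37-fold, 7.26-fold, 6.78-fold and 6.56-fold lower. Prl2c2 was 6.65-fold lower but shares 80.0% of its windows with related genes and is uncertain.

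**Figure D2:**
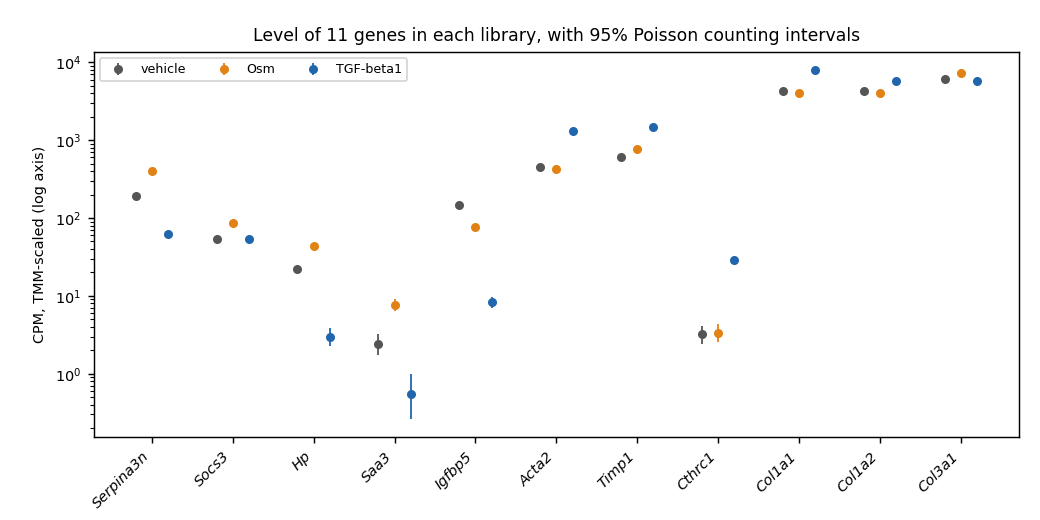
Level in CPM on a log axis of 11 named genes in the vehicle, Osm and TGF-beta1 libraries (1 library each); bars are exact 95% Poisson intervals of the count and cover counting error only. Acta2 is at 445.6, 421.7 and 1327 CPM and Serpina3n at 192.8, 397.1 and 63.2 CPM in the vehicle, Osm and TGF-beta1 libraries.

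The lists of collagen chains, collagen processing, contractile, integrin and TGF-beta/Smad response genes stood above the random range. The collagen chains had a median log2 ratio of 0.41 (percentile 99.99), with 4 of 22 at least 2-fold higher, 4 at least 2-fold lower and 14 between. Col8a2 was the highest, and Col14a1, a fibril-associated collagen, was 2.79-fold lower (2.58 to 3.01). Myofibroblast contractile genes had a median of 0.37 (percentile 99.99), with 2 of 22 higher, Acta2 and Tagln, and none lower. The abundant Flna and Cald1 were 1.31-fold and 1.24-fold higher, short of the rule. Collagen processing and crosslinking genes had a median of 0.25, with 4 of 23 higher and none lower. Among them P4ha3, a collagen prolyl hydroxylase subunit, was 2.84-fold higher (2.22 to 3.68) and the collagen chaperone gene Serpinh1 1.29-fold higher (1.27 to 1.31). Integrins and focal adhesion genes had a median of 0.24, with 3 of 25 higher and 1 lower, Sdc4 (2.04-fold, 1.88 to 2.21). The TGF-beta/Smad response genes had a median of 0.19, with 6 of 31 higher and 1 lower. Lrrc15, a marker of TGF-beta-activated fibroblasts, was at 0.326 CPM with vehicle and 6.24 CPM with TGF-beta1 (17.7-fold, 8.53 to 53.2), and Il11 was 3.43-fold higher (2.95 to 4.01). Ccn2 was 1.96-fold higher (1.93 to 2.00), short of the rule.

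Among the other matrix proteins, 7 of 39 were at least 2-fold higher and 6 at least 2-fold lower. Their median of -0.13 lay below the random range, while their mean of 0.11 had the opposite sign. Cthrc1 and Mfap4 were the named members that were higher, while the abundant fibronectin gene Fn1 was at 16670 CPM with vehicle and 12480 CPM with TGF-beta1 (1.34-fold lower, 1.33 to 1.34). Bgn, which encodes biglycan, was 1.07-fold higher. The cell cycle genes had a median of 0.52 (percentile 100), with 31 of 35 above 0 and 2 at least 2-fold higher. Rrm1, a subunit of ribonucleotide reductase, was 1.70-fold higher (1.57 to 1.84), Ube2c 1.95-fold higher (1.38 to 2.80) and Ccna2 1.90-fold higher (1.47 to 2.49), none past the rule. The unfolded protein response genes had a median of 0.36 (percentile 100), with 23 of 25 above 0 and none past the rule. The chaperone gene Hspa5 was 1.44-fold higher (1.41 to 1.46), Asns 1.72-fold higher (1.65 to 1.79) and Hyou1 1.60-fold higher (1.54 to 1.65).

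The complement and acute-phase genes stood furthest below the random range, with a median of -1.30 (percentile 0), all 16 measured members below 0 and 14 of them at least 2-fold lower. Their summed level was 5162 CPM with vehicle, 5712 CPM with Osm and 2267 CPM with TGF-beta1. Hp was 7.37-fold lower (5.60 to 10), the lipopolysaccharide-binding protein gene Lbp 4.01-fold lower (3.52 to 4.58), Serping1 2.55-fold lower (2.48 to 2.62) and C4b 2.37-fold lower (2.32 to 2.42). The gp130/Stat3 list shares Hp, Lbp, Lcn2, Saa3 and Serpina3n with this list. The mural cell markers had a median of -0.51, with 5 of 11 lower and 1 higher and a summed level of 136.4 CPM with vehicle and 151 CPM with TGF-beta1, or 127.9 and 76.1 CPM without Cspg4, which alone turned the sum upward. The endothelial markers had a median of -0.71, with 2 of 6 lower and a summed level of 90.9 and 60.6 CPM. The adipogenic and adipocyte genes had a median of -0.69, with 8 of 22 lower and none higher. Apoe was 4.28-fold lower (4.06 to 4.51), and Scd1, a fatty acid desaturase at 5756 CPM with vehicle, was 1.75-fold lower (1.73 to 1.76). Fasn, the fatty acid synthase gene, was 1.01-fold lower (0.992 to 1.03), a difference within counting error. The proteases and inhibitors of matrix turnover had a median of -0.59 with 5 of 29 higher and 5 lower. The urokinase gene Plau was 4.61-fold lower (4.37 to 4.86), the stromelysin gene Mmp3 3.25-fold lower (3.16 to 3.34) and Timp1 2.48-fold higher (2.42 to 2.53).

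The Wnt and BMP pathway genes had a median of -0.51, with 4 of 27 higher and 9 lower. Sfrp2, a secreted Wnt modulator, was 6.25-fold lower (5.26 to 7.51) and Id3, a BMP target, 3.13-fold lower (2.75 to 3.58). The interferon response genes had a median of -0.39, with 1 of 29 higher and 3 lower, and the immunoproteasome gene Psmb8 was 2.45-fold lower (1.99 to 3.04). The progenitor genes had a median of -0.37, with 1 of 25 higher and 5 lower. These went in different directions: Pi16, a marker of universal fibroblasts, was 4.39-fold higher (3.89 to 4.99) and Ly6a, which encodes Sca-1, 3.80-fold lower (3.61 to 4.0). Chemokines and cytokines had a median of -0.27, with 2 of 19 higher and 5 lower, and Cxcl5 was 5.98-fold lower (4.81 to 7.59). The receptors and signal transducers had a median of -0.25 with none of 21 past the rule, Lifr at 1.96-fold lower (1.80 to 2.14). The antioxidant genes had a median of -0.15, with 2 of 25 lower, Gstm1 (2.38-fold, 2.28 to 2.49) and Gsta4 (2.16-fold, 1.96 to 2.38). Ly6a, Gstm1 and Mmp3 belong to gene families and share 16.1%, 17.4% and 13.7% of their windows with another gene.

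Several members past the 2-fold rule were named only after their values were seen. Besides Col8a2, the collagen chains that were higher with TGF-beta1 were Col7a1 (log2 ratio 1.77), Col15a1 (1.08) and Col16a1 (1.07), and besides Col14a1 those lower were Col27a1 (-1.26) and the collagen VI chains Col6a3 (-1.14) and Col6a1 (-1.02). The crosslinking enzyme gene Loxl2 and the hydroxylase gene P3h2 were both at 1.02, and the integrins that were higher were Itga2, Itga3 and Itga7. Tgfbi was the TGF-beta/Smad member that was lower (-1.22), and Bub1 and Ccne2 were the cell cycle members that were higher. Genes higher in the Wnt and BMP list included Wnt5a, Wnt11 and Ccn4. Among the proteases and inhibitors, those higher included Mmp10, Mmp13, Timp3 and Timp1, and those lower were Mmp8, Timp2, Serpine2, Plau and Mmp3. Lower progenitor genes besides Ly6a were F3, Gdf10, Il33 and Sfrp4, and lower chemokines and cytokines besides Cxcl5 were Ccl8, Ccl11, Cxcl1 and Il33, while Il11 and Lif were higher. In the interferon list Gbp3, Psmb8 and Psmb9 were lower and Rsad2 higher (2.09). In the growth factor list Igfbp2, Pdgfc, Gdf6 and Hbegf were higher, and Igfbp4, Igfbp5, Vegfd, Gdf15 and Angpt2 lower.

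Within the random range lay the gp130/Stat3 response genes (median -0.03), with 2 of 37 higher and 8 lower, and Socs3 was at 54.3 CPM with vehicle and 54.5 CPM with TGF-beta1. The growth factors and IGF axis had a median of -0.04, with 4 of 31 higher and 5 lower. Nuclear-encoded oxidative phosphorylation genes (median 0.14), AP-1 and immediate early genes (0.04) and the mitochondrially encoded genes (0.01) held no member past the rule. Cholesterol synthesis also held none, with a median of 0.00. In glycolysis (median 0.01, mean -0.20) and the reference housekeeping genes (median 0.07, mean -0.14), Gapdh was the single member past the rule. The medians of cholesterol synthesis, glycolysis and the mitochondrially encoded genes changed sign between scalings of the libraries, within -0.02 to 0.01.

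Markers of other cell types also differed between these libraries. The mural cell markers lower with TGF-beta1 (percentile 0.30 for the list) were Steap4 (3.42-fold, 2.93 to 4.02), Ndufa4l2 (2.60-fold, 2.20 to 3.10) and, named after their values were seen, Rgs4, Abcc9 and Vtn, while Cspg4 was higher. Ndufa4l2 overlaps Shmt2, on the opposite strand. The endothelial markers that were lower (percentile 1.03 for the list) were Cdh5 and Vwf, and Vwf was at 6.2 CPM with vehicle and 1.57 CPM with TGF-beta1. The mesothelial markers lay within the random range, with a median of -0.18 and a mean of 0.02. The leukocyte markers, with 4 measured, summed to 24.1 CPM with vehicle, 20.9 CPM with Osm and 17.6 CPM with TGF-beta1. Those of mature adipocytes, with 2 measured, summed to 26.0, 26.9 and 15.5 CPM, and those of Schwann cells, with 2 measured, to 267, 258 and 291 CPM. Pmp22 alone was at 255.9, 247.4 and 279.7 CPM, so the Schwann cell sum rests on 1 gene. Of the erythroid markers only Epor was measured, at 1.2, 0.403 and 0.163 CPM.

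**Figure D3:**
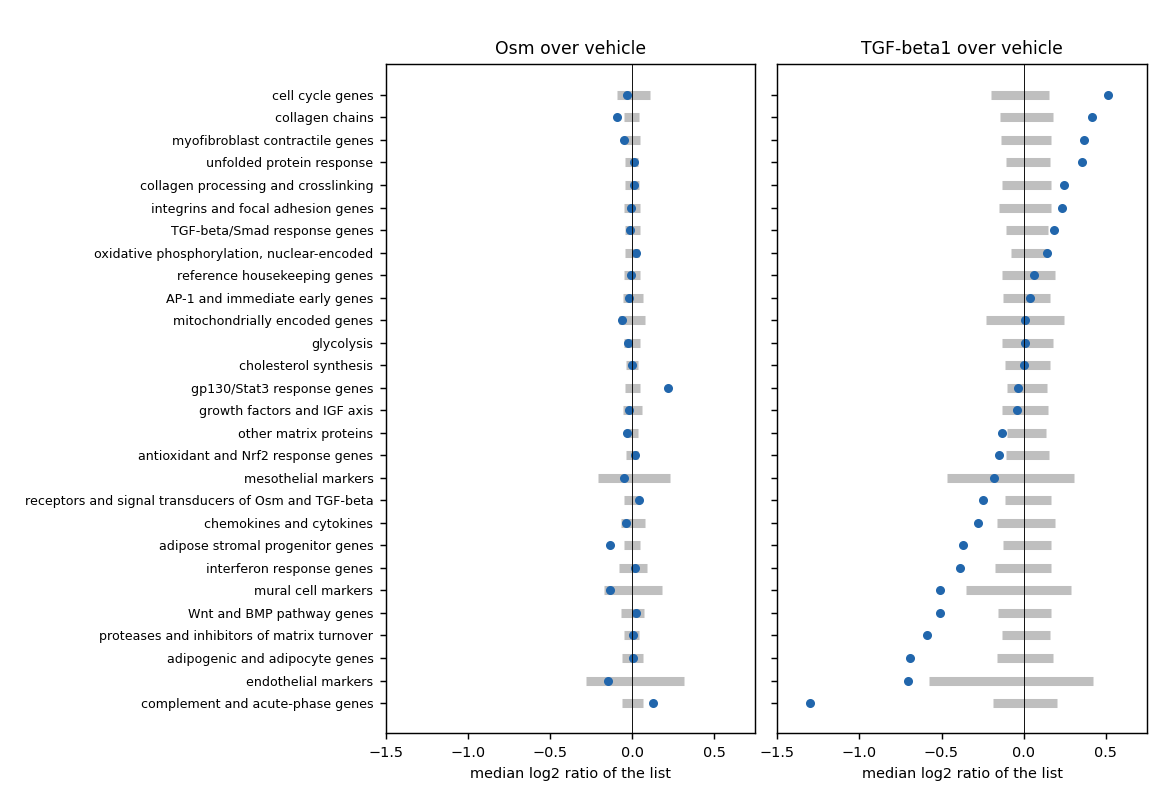
Median log2 ratio over vehicle of the 28 gene lists with at least 5 measured members (blue points), for the Osm library and for the TGF-beta1 library; grey bars span the central 95% of 10000 random lists of the same size matched on expression. Points outside the bars number 5 for Osm and 19 for TGF-beta1, where the lowest is the complement and acute-phase list at -1.30.

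Set directly against each other, the Osm library had 13 of 16 complement and acute-phase genes at least 2-fold higher than the TGF-beta1 library and 2 of 22 contractile genes, Acta2 and Tagln, at least 2-fold lower. Hp was at 43.8 CPM with Osm and 2.98 CPM with TGF-beta1, 14.6-fold higher (11.2 to 19.7). The low Saa3, at 7.72 CPM with Osm and 0.543 CPM with TGF-beta1, was 13.6-fold higher (7.50 to 30.4). Col8a2 was 17.8-fold lower with Osm (13.9 to 23.4), Cthrc1 8.64-fold lower (6.63 to 11.6) and Acta2 3.15-fold lower (3.07 to 3.23). In total 696 genes were at least 2-fold higher and 332 at least 2-fold lower with Osm than with TGF-beta1, and 221 and 107 of them reached 10 CPM in either library. Simulated unchanged libraries with an assumed coefficient of variation of 0.2 gave 62 to 117 higher and 69 to 118 lower, a range that holds the 107. With 0.1 the means were 0.13 and 0.13. As said above, 0.2 gave far more such genes for Osm over vehicle than were observed.

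Among protein-coding genes at 10 CPM or more, others at the top of this comparison were Gdpd2 (14.2-fold, 8.39 to 28.2), Csmd1 (11.3-fold, 7.31 to 19.3), Igfbp5 (9.25-fold, 7.85 to 11), Cxcl5 (8.66-fold, 7.0 to 11) and Ahsg (8.32-fold, 6.50 to 10.9). Csf2rb, Col23a1, Kng2 and Sfrp2 were 7.75-fold, 7.39-fold, 7.13-fold and 7.05-fold higher, where Csf2rb and Kng2 share 12% and 19.2% of their windows with another gene. Lower with Osm were Lrp2, an endocytic receptor (10.3-fold, 6.80 to 17.1), and Cspg4 (10.1-fold, 8.46 to 12.3). Notch4, Ncam1, Adamts8 and Mfap4 were 7.11-fold, 7.03-fold, 7.01-fold and 6.39-fold lower. Cilp, a matrix protein gene, was at 199.0 CPM with Osm and 1198 CPM with TGF-beta1 (6.02-fold lower, 5.81 to 6.24), and Fgf21 was 5.48-fold lower (3.96 to 7.91).

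Of the 28 lists, 11 stood above and 7 below the random range in this comparison. The complement and acute-phase genes had a median of 1.42, with 13 of 16 at least 2-fold higher with Osm. The adipogenic genes had a median of 0.64, with 6 of 22 higher, and the proteases of 0.61, with 6 of 29 higher and 4 lower. The gp130/Stat3 response genes had a median of 0.33, with 8 of 37 higher and 1 lower, and Socs3 was 1.60-fold higher (1.47 to 1.73). Wnt and BMP pathway genes (0.48), interferon response genes (0.41), receptors (0.32), progenitor genes (0.28) and antioxidant genes (0.17) were above as well, as were the endothelial (0.64) and mural (0.58) markers. Below the range lay the cell cycle genes (-0.45), the collagen chains (-0.39, with Col6a3, Col14a1 and Col27a1 higher and Col7a1, Col8a2, Col12a1, Col15a1 and Col16a1 lower) and the myofibroblast genes (-0.38). The TGF-beta/Smad genes (-0.36), the unfolded protein response (-0.35), collagen processing (-0.26) and the integrins (-0.24) lay below it too. Ccn2 was 2.07-fold lower with Osm (2.03 to 2.11), Col1a1 2.00-fold lower (1.98 to 2.02, just short of the rule) and Timp1 1.94-fold lower (1.90 to 1.98). Col3a1 was 1.28-fold higher with Osm (1.27 to 1.29).

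Few genes differed from vehicle in both treated libraries. At least 2-fold higher in both were 20 genes, of which Sorcs2 and the pseudogene Gm10241 reached 10 CPM in at least 1 library. Sorcs2 was at 1.85 CPM with vehicle, 4.03 CPM with Osm and 17.1 CPM with TGF-beta1. At least 2-fold lower in both were 36 genes, of which Gapdh and the pseudogene Gm12751 reached that level. Opposite differences were found in 6 genes higher with Osm and lower with TGF-beta1, where independent lists would share 6.23, and in 5 genes the other way, where they would share 2.02. The former included Serpina3n and Csmd1, lower with TGF-beta1 by 3.05-fold (2.86 to 3.27) and 5.64-fold (3.56 to 9.78), and the latter Col8a2, Lrp2 and the predicted gene Gm32255.

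Both ratios share the vehicle library. Independent lists of these sizes would share 2.95 genes upward and 4.26 downward, and unchanged libraries against the same vehicle shared a mean of 3.77 and 2.69 with counting error alone. With an assumed coefficient of variation of 0.1 they shared 8.60 and 4.76, and with 0.2 they shared 52.7 and 29.3, against the 20 and 36 observed. Across genes, which are not independent replicates, the log2 ratios of the ligands had a Pearson correlation of 0.23. Simulated unchanged libraries gave a mean of 0.49 with counting error alone and 0.50 with an assumed coefficient of variation of 0.1 or 0.2. The shared vehicle library sets that value, and differences in only 1 treated library lower it. The 0.23 therefore does not measure how alike the ligands acted. The covariance of the ratios was 0.0444 against a simulated 0.0208 with counting error alone, a difference of 0.0236, and a simulated 0.0426 and 0.109 with assumed coefficients of variation of 0.1 and 0.2. The vehicle library cannot be split, so part of any excess may come from the shared control.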

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

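The filter at 10 CPM was chosen only after the results were seen, and all other alternatives were fixed before the data were examined. No paired analysis was possible because each condition had 1 library. Counts below are of genes higher, then lower, against main counts of 130 and 89 for Osm over vehicle, 311 and 657 for TGF-beta1 over vehicle, 696 and 332 for Osm over TGF-beta1, and 20 and 36 in both ligands. Under total counts, DESeq2 size factors, upper-quartile factors and the library size without the mitochondrial and 20 most abundant genes, these counts and the correlation of 0.23 stayed within their limits, which were 1.5 times for a count and counting error for the correlation. Over all alternatives, 66 of these values did so and 57 did not, and no value past its rule changed direction. Of the list medians 939 stayed within counting error and 18 did not, and of the ratios of named genes 3866 did and 36 did not.

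Where an alternative changes the genes tested or the fold required, its construction shows why the counts differ. Without a filter, Osm over vehicle gave 237 and 231 genes, both ligands shared 33 and 75, and the correlation was 0.45. At 5 CPM, Osm over vehicle gave 13 and 10, TGF-beta1 over vehicle 124 and 306, Osm over TGF-beta1 308 and 144, and both ligands 4 and 3, with a correlation of 0.15. At 10 CPM the counts were 7 and 7, 93 and 228, 226 and 107, and 2 and 2, in the same order, with a correlation of 0.14. With protein-coding genes only, Osm over vehicle gave 48 and 54 and both ligands 10 and 20, so that 47.1% of the Osm calls were higher against 59.4% in the main count. At a fold of 1.5 the counts were 288 and 228, 823 and 1307, 1361 and 845, and 55 and 93. At a fold of 4 they were 17 and 8, 57 and 128, 137 and 57, and 3 and 3. With the interval wholly beyond 2-fold they were 13 and 5, 116 and 252, 253 and 125, and 2 and 1. A prior count of 5 gave 82 and 59 for Osm over vehicle and 13 and 16 for both ligands, and the authors' FPKM gave 12 and 23 for both ligands; for these the cause was not tested. The median of the collagen chains in Osm over TGF-beta1, -0.39, was -0.50 without a filter and -0.28 at 5 CPM, where the measured members differ. Depth limits the genes under 10 CPM, where most Osm calls lay.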

Other observations

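Of the tests below, those of glycolysis genes, of spread between cultures and of the complement genes, and the count of genes by shared windows, were chosen only after the result was seen.

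The Osm library differed from vehicle 2-fold in 10 genes at 10 CPM or more, and Gapdh and pseudogenes were among them. Counting error alone is argued against, since 0 such genes was the highest number in 100 simulations. A lower level of glycolysis genes as a whole is argued against for Gapdh, since 0 of the 20 other measured glycolysis genes were 2-fold lower with Osm. Reads shared with near-identical copies may have contributed, and stay open: 20.8% of the windows of Gapdh occur in another gene, and the median over the 10 genes was 21.9% against 0% in genes not counted, with 4 of the 10 at 50% or more. Neither value reached the level set for this explanation or fell below the level set against it. At 10 CPM or more, 6 of 466 genes with at least 20% of windows shared differed 2-fold against 4 of 8712 with less. Those 6 were Gapdh, Rps27a and 4 processed pseudogenes. No other biological explanation for Gapdh was tested.

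Most of the 2-fold differences between the Osm and vehicle libraries, 209, lay in genes under 10 CPM, 96 of them protein-coding and 113 not. Of all 13712 tested genes, at any level, 12049 were protein-coding, a larger share than among the 209. The share among tested genes under 10 CPM was not computed, so this does not set the 209 apart from other genes at their level. Counting error as the whole source is argued against, since the highest number in 100 simulations was 68. Spread between cultures or libraries would have to be large: an assumed coefficient of variation of 0.1 gave a mean of 79.0 such genes and 0.2 a mean of 263.2, but 0.2 also gave 181 genes at 10 CPM or more, where 10 were seen. The ratios of genes at 50 CPM or more corresponded to 3.25%. With no replicate the spread of genes under 10 CPM was not measured, so it cannot be told apart from an effect of Osm on these genes. Whether reads shared with near-identical copies contributed to these differences was not tested and stays open.

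The complement and acute-phase genes were lower with TGF-beta1, with a median log2 ratio of -1.30, and the scaling of the libraries is argued against, since the highest median under the 4 other scalings was -1.30 and the lowest -1.32. Fewer leukocytes, endothelial, mural or mesothelial cells were weighed by level. With vehicle their markers summed to 24.1, 90.9 (Tek 48.5), 136.4 (Steap4 38.9) and 187.6 CPM (Cldn15 94.6) in cells depleted of CD45 and CD31. The complement list's summed level was lower by 2895 CPM. This comparison cannot exclude a loss of any of these cells, since their complement level relative to their markers was not measured. The median ratio of the mesothelial markers (95% bootstrap interval -0.26 to 0.75) lay above -1.30, which argues against their loss as the whole source. The endothelial interval (-1.60 to -0.02) lay below 0 and included -1.30, which goes with fewer such cells. The mural interval (-1.38 to 0.37, with 2 markers also in other lists) included both. Fewer endothelial cells, mural cells or leukocytes therefore stay open, as a part or the whole of the source. Spread between cultures also stays open, so a lower expression of these genes in TGF-beta1-treated fibroblasts may be the source only as a hypothesis. Replicate cultures of each condition would test the spread, but not which cells the RNA came from.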
